A study of Nothobranchius furzeri with 10 samples.

How the data were processed

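The samples were total RNA from brains of male GRZ-strain killifish at 10 weeks of age, prepared with an Illumina TruSeq RNA v2 kit per the labels' protocols. All 10 libraries carry the same label, swim tunnel, and form 1 group. Libraries are numbered 1 to 10 in accession order, and the numbers served as names and were not used to order or pair samples. The submitters' processing notes name bcl2fastq 1.8.4, STAR 2.4.1d and featureCounts 1.4.6-p4. The genome build, the annotation, the counting options and the use of strand are not given in the sources used here, so reads shared between near-identical copies or overlapping genes may have been split or dropped in ways that cannot be traced.

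The authors deposited a table of raw counts per gene and a table of RPKM (reads scaled by gene length and library total), each with 26739 genes and 1 column per library. Every column belonged to one of the 10 samples by its title, so 0 columns were left out, and 0 rows lacked a gene. The count table was used for all tests. The deposited RPKM values did not follow from the counts of their own column. In 9214 genes with at least 200 counts and an RPKM of at least 5 in all libraries, the gene length implied by count, RPKM and the column's own total differed between libraries with a median coefficient of variation of 11.0% and a maximum of 14.8%. When the divisor was taken from the 10 library totals in turn, moving to the next total with each row and on across the columns, the median fell to 0.00158% and the maximum to 0.00648%. The same cycle begun at any of the other 9 totals left a median of at least 9.70%. Of 217396 nonzero RPKM values, 99.97% lay within 0.001 RPKM or 0.1% of the value made with cycled totals, and 11.7% within that tolerance of the value made with the column's own total. The deposited RPKM were thus between 0.813 and 1.23 times the RPKM made with own totals, with an SD of the log2 ratio of 0.15, and were not used to compare libraries. They served to recover gene lengths, which came out for 22871 genes with a median of 2380 bp, 50.0% of them divisible by 3.

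The gene identifiers were looked up in a RefSeq gene table of the species with 38438 genes (assembly NfurGRZ-RIMD1) and 0 of 26739 matched in any of its identifier columns. The files do not pair the identifiers with names. Gene lists for cell types, stress, activity and metabolism, relations between them, and pairs of duplicated genes had been fixed before the data were examined, and none of them could be evaluated. The rule for named genes, fixed at the same time, was for this case to print at most 2 identifiers at each end of the ranking by spread: the highest BCV among genes of at least 5 CPM whose call held without each library in turn, and the lowest.

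Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes with a mean of at least 1 CPM were kept, libraries were scaled with TMM, and a negative binomial model with an intercept and no covariate was fitted with the trended dispersion. The deviance of each gene was compared with a chi-square distribution with 9 degrees of freedom (upper tail), and p-values were adjusted by Benjamini-Hochberg over the 17951 genes. The trend lay above most genes: 84.0% of them had a BCV below it, and the median deviance was 2.57, so the test is strict for the typical gene. It was tested on simulated data with the real means and totals for 17951 genes, of which 100 had a dispersion 4 times and 100 a dispersion 10 times the trend. It recovered 47% of the former and 93% of the latter, and 5 of its 145 calls (3.45%) were false. The unchanged genes of the simulation had a dispersion on the trend and varied independently of each other. In the data most genes lay below the trend and many varied together, so these rates may not hold there. The level of a gene is given as CPM with TMM scaling. The filter, the description of abundance, the slopes on gene length and the comparison of excess levels in libraries 1 and 7 instead used CPM by library total. Log2 CPM used a prior count of 2, except in the slopes on gene length, where a constant was added to CPM.

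Modules were made from the log2 CPM of the called genes by average linkage on Pearson correlation, with the tree separated at a correlation of 0.5 and groups of at least 20 genes kept. Principal components were computed on log2 CPM of all 17951 tested genes in Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3. The shares of the first 2 were compared with 100 data sets in which libraries were permuted within each gene. Relations to total counts, genes detected, the share of counts in the 10 most abundant genes and the slope on gene length were tested with 100000 permutations, 2-sided, with adjustment over the 8 relations. The step was tested on simulated data with a planted axis.

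Alternatives planned before the data were examined were scaling by DESeq2 size factors and by library size alone, other abundance filters, dispersion outliers of DESeq2 1.42.0, a limma-voom F test of limma 3.58.1, the first principal component as a covariate and, for the count of variable genes, leaving out each library in turn. For the principal components they were DESeq2 size factors, the 1000 genes of highest variance and a minimum of 5 CPM. Those added after the data had been seen were a running-median trend over 501 genes, removal of the gene-length trend, deposited RPKM scaled back to counts, removal of libraries 1 and 7 together, principal components without each library in turn and without the variable genes, and all settings of the modules.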

Results

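Brain RNA was sequenced from the turquoise killifish Nothobranchius furzeri, a short-lived annual fish used to study ageing. The 10 libraries came from male fish of the GRZ strain at 10 weeks of age. The labels place all of them in 1 group with the perturbation swim tunnel, a chamber in which fish swim against a flow of water. The labels give no group without this perturbation among these samples. The question the data can address is how far brain expression differed from library to library, and which genes differed together. The count table held 26739 genes, and the gene identifiers are not paired with gene names in the files. Totals per library ranged from 22958779 to 28223263 counts, with a mean of 25327626 ± 1990858 (SD, n = 10). At these totals 3 counts corresponded to 0.106 to 0.131 CPM (counts scaled to a library total of 1000000), a floor that covers counting error only. Nothing in the labels says that the libraries came from separate animals, so the p-values below measure only the spread between these samples, which may be technical. Over 16633 genes with a mean of at least 50 counts, chi-square per degree of freedom lay between 9.58 and 70.8 in the 45 pairs, so no pair was treated as a library deposited more than once. That does not show whether any pair came from the same fish.

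Expression in the brain libraries was broad, with no small set of genes taking most of the counts. A total of 17951 genes had a mean of at least 1 CPM, 12085 at least 10 CPM, 2413 at least 100 CPM and 51 at least 1000 CPM. The 1479 most abundant genes together held 50% of the expression, and 7912 genes held 90%. The most abundant gene reached 6686 ± 710 CPM (SD, n = 10). The 10 genes of highest mean CPM, the same 10 in each library, took between 3.45% and 3.97% of a library's counts. Each library detected between 21612 and 21908 genes, and 20436 genes were counted in every library. A further 3868 genes (14.5% of those listed) had 0 counts in all libraries, which over 253276258 counts allows a level of up to 0.0118 CPM.

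Most brain genes differed little between libraries, and a minority of 1213 genes differed far more than other genes of their abundance. The biological coefficient of variation (BCV) stands for the spread between libraries beyond counting error. Here it is edgeR's estimate for each gene, which is drawn toward the dispersion trend of genes of similar abundance. Its median was 0.152 over the 17951 genes tested. It was 0.606 among the 1213 genes past the test, 6.76% of those tested, and 0.145 among the others. In steady genes the estimate can exceed the whole spread. Nfu_g_1_017829 had a BCV of 0.0678 and a coefficient of variation, counting error included, of 1.27%. The SD of log2 CPM had a median of 0.97 in the genes past the test and of 0.18 over all genes. The range over the 10 libraries was more than 2-fold in 21.2% of the genes tested, so ranges of that size were not confined to the genes past the test. The range includes counting error and was not split by abundance, so it does not show how many other genes differed beyond noise. Variable genes occurred in each of 3 abundance classes: 535 of 5861 genes under 10 CPM passed (9.13%), 547 of 9670 genes from 10 to 100 CPM (5.66%) and 131 of 2420 genes of at least 100 CPM (5.41%), with levels here scaled by TMM and not by library total as in the counts of genes above. Their median length was 2977 bp, against 2760 bp for the other genes. It differed between the groups of variable genes (modules) described below, from 1904 bp in module 6 to 3786 bp in module 5. The 2 largest, modules 1 and 2, had 3313.5 bp and 2718 bp. The test was the deviance of each gene in an edgeR fit with a common mean, set against the dispersion trend of genes of similar abundance, with Benjamini-Hochberg adjustment at 0.05. Of the 1213 genes, 747 (61.6%) passed again in each of the 10 fits that left out 1 library. The number depended on where the trend lay and on the tool. DESeq2 marked 296 genes as dispersion outliers, and an edgeR trend through the running median called 4200. A limma-voom F test called 0 genes, with 1124 of the 17951 at an unadjusted p under 0.05. That test compares each gene with a spread of variances fitted to these same genes, the variable ones included. A call was therefore hard to reach, and its 0 decides nothing about the 1213 genes.

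**Figure D1:**
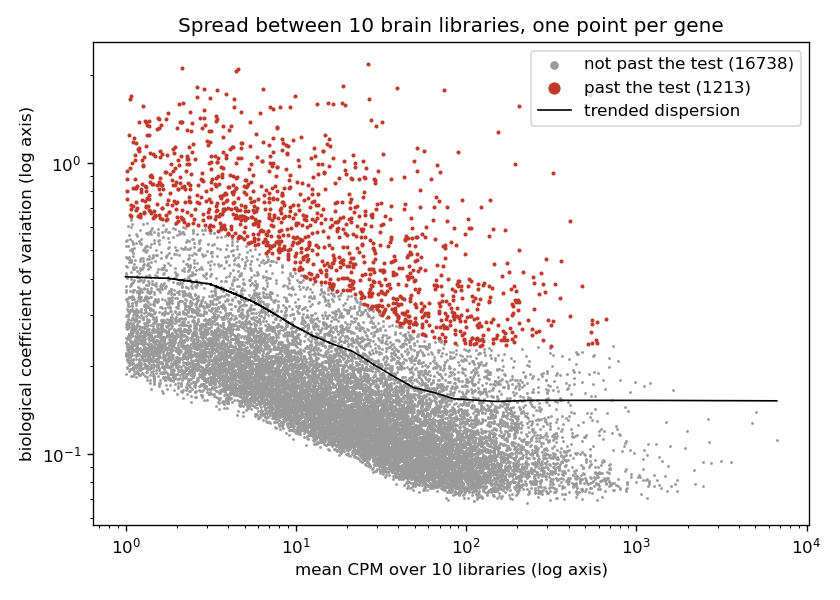
Biological coefficient of variation between the 10 libraries against mean CPM, both on log axes, with 1 point per gene and the trended dispersion as a line. The 1213 genes past the test (red) lie above the trend, and the other genes (grey) have a median of 0.145.

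Of the genes with a mean of at least 5 CPM whose call held in every fit without 1 library, Nfu_g_1_003954 varied the most. It had a mean of 26.5 ± 51.8 CPM (SD, n = 10) and a BCV of 2.18 where the trend was 0.209 (edgeR, adjusted p = 1.85e-235). Its counts were 2448 in library 1, 3356 in library 7 and 409 in library 3, with 29 in library 5 and between 0 and 9 in the remaining 6 libraries. The gene Nfu_g_1_017941 was next, with a mean of 19.0 ± 19.6 CPM and a BCV of 1.83 against a trend of 0.231 (edgeR, adjusted p = 3.51e-111). Libraries 3, 4, 6, 9 and 10 held between 890 and 1018 counts of Nfu_g_1_017941, library 5 held 73, and libraries 1, 2, 7 and 8 held 0 or 1. At the other end, Nfu_g_1_017829 was nearly constant at 227 ± 2.88 CPM (SD, n = 10), a coefficient of variation of 1.27%, and Nfu_g_1_000251 at 112 ± 2.14 CPM, 1.91%.

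The variable genes rose and fell together in a few large groups. Clustering by correlation over the 10 libraries placed 1134 of the 1213 genes (93.5%) in 6 groups of at least 20 genes, called modules here, while the largest group in 100 data sets with libraries permuted within each gene had 34 genes. Modules 5 and 6, with 22 and 21 genes, are smaller than that, so their size does not set them apart from permuted data. This clustering was chosen after the data had been seen, and the number of modules fell to 2 when it used only the 747 genes that held without each library in turn, and to 3 without library 3 and 3 without library 10. Module 1 held 490 genes with a mean pairwise correlation of 0.897. Its genes were low in library 7, at a median of 0.390 times each gene's own median, in library 9 at 0.430 times and in library 10 at 0.436 times, and library 2 followed at 0.615 times. The same genes were high in library 3 (1.55 times), library 4 (1.54 times) and library 1 (1.42 times). Libraries 7, 9 and 10 also had the lowest slopes on gene length (-0.0250, -0.0262 and -0.0142 per doubling), the highest shares of counts in the 10 most abundant genes (3.87%, 3.97% and 3.67%), the fewest genes detected (21673, 21614 and 21612) and the highest scores on the second principal component described below (0.446, 0.213 and 0.179). The module's score had r = -0.908 with the second component. That component was computed with the module's genes included, so the agreement of the 2 is not separate evidence. None of the 490 genes was above its own median in library 7. Module 1 took between 1.21% and 3.26% of the counts of a library, and 365 of its genes held without each library in turn.

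Module 2 held 458 mostly low-abundance genes, with a median level of 5.99 CPM, that were high in 2 libraries. Their median was 5.24 times the gene's own median in library 1 and 4.37 times in library 7. Library 3 was at 1.55 times and the other 7 lay between 0.772 and 1.06 times. The module took between 0.420% and 1.97% of a library's counts. Without library 1, 315 of the 458 genes passed the variability test, and without both library 1 and library 7, 97 did. With the first principal component described below as a covariate, 204 did. The module's score had r = 0.905 with that component, which was computed with the module's genes included. Library 1 also had the most genes at 1 CPM or more, 18169, against 17739 in library 7.

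The other modules were smaller, had different profiles and depended more on the settings. Over 16 other settings of the clustering, modules 1 and 2 were each found again with a Jaccard overlap of at least 0.5 in all 16, module 3 in 10, module 4 in 6, module 5 in 11 and module 6 in 8. The overlap was 0 in 5 settings for module 5 and in 8 for module 6. Module 3 (76 genes) was set by library 10 alone: its genes there were at a median of 0.20 times their own median, against 0.952 to 1.18 times in the other 9 libraries. Without library 10, 13 of the 76 genes passed the variability test. Module 4 (67 genes) was between 1.27 and 1.68 times the gene median in libraries 1, 2, 3, 4 and 5 and between 0.651 and 0.797 times in libraries 6, 7, 8, 9 and 10. The 22 genes of module 5 had the opposite profile, at 0.694 to 0.794 times in libraries 1, 2, 3, 4 and 5 and 1.21 to 1.55 times in the rest. The labels name no difference between these libraries, but the split runs along the order of accessions and of the numbers in the sample titles, which skip 1 number between libraries 5 and 6. A batch or a group missing from the labels is not excluded, and the 2 sets were not compared. Module 6 (21 genes, among them Nfu_g_1_017941) was low in libraries 8, 1, 7 and 2, at 0.154, 0.224, 0.248 and 0.381 times the gene median. Its level was 0.778 times in library 5 and between 1.29 and 2.07 times in libraries 3, 4, 6, 9 and 10.

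**Figure D2:**
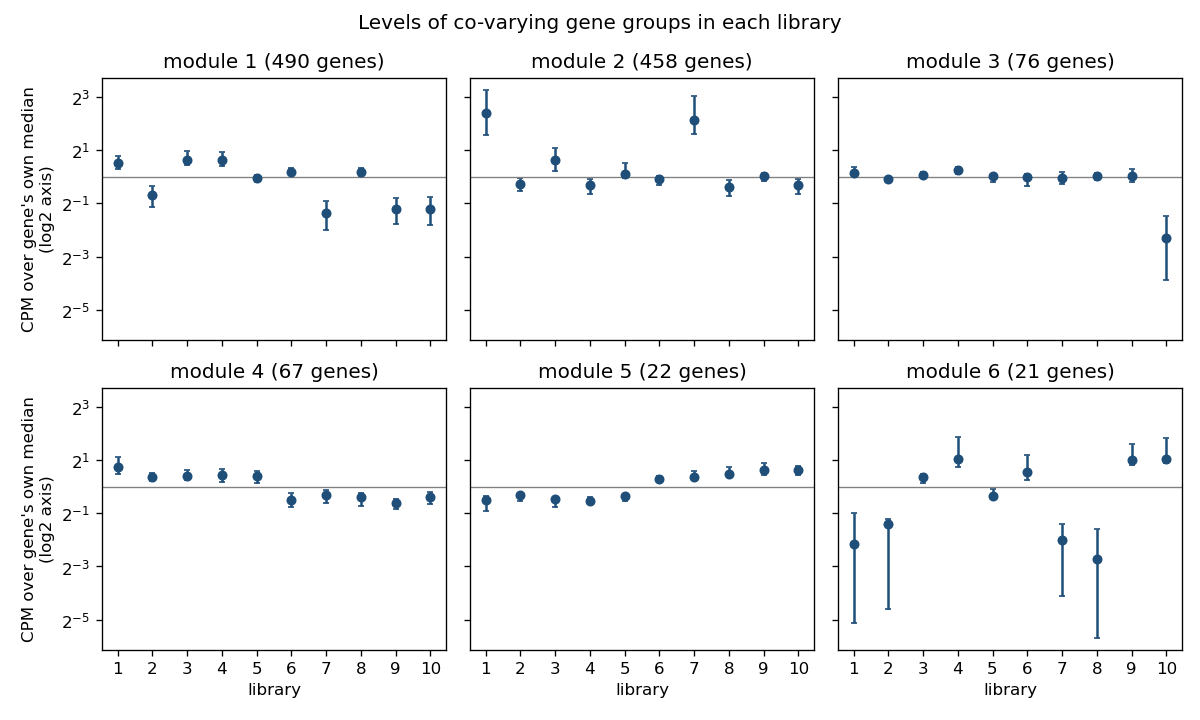
Level of each module in each of the 10 libraries, as CPM over the gene's own median over libraries, on a log2 axis. Points are medians over the module's genes, bars run from the 25th to the 75th percentile, and the grey line marks 1: module 1 is lowest in libraries 7, 9 and 10, module 2 highest in libraries 1 and 7, and module 3 low in library 10.

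The largest part of the variation between libraries lay on the first 2 principal components. The first principal component of log2 CPM held 35.8% of the variance and the second 30.8%, against at most 13.5% and 12.6% in 100 data sets with libraries permuted within each gene (permutation p = 0.0099 for each, the smallest they can give). The third held 8.48%. The 1213 variable genes, 6.76% of the genes, held 63.6% of the variance, a share that their selection for large spread raises by construction. Module 2 held 29.8% of the variance and module 1 19.7%. Without the 1213 genes, a setting added after the data had been seen, both components together still held 56.1%, against 66.6% with them. Library 1 lay at one end of the first component and supplied 50.2% of its sum of squares, and library 7 supplied 43.8% of the second. The largest gap between neighbouring libraries was 33.0% of the range on the first component and 31.0% on the second, in each case between that library and the rest.

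**Figure D3:**
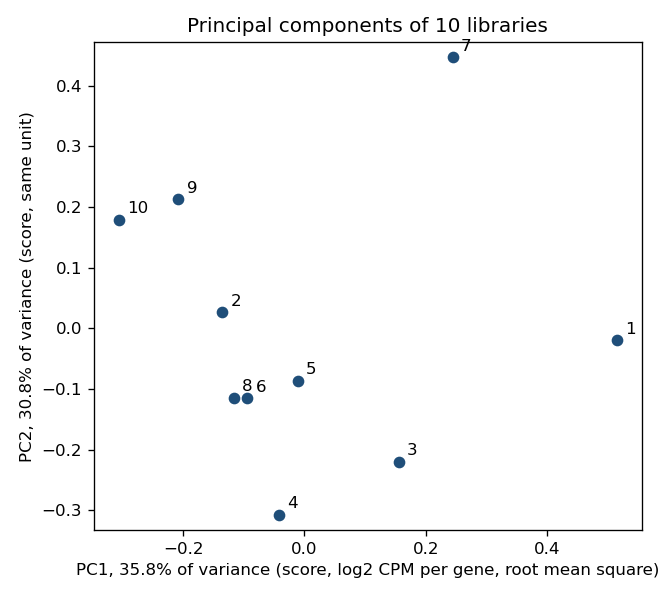
Scores of the 10 libraries, marked by their numbers, on the first and second principal components of log2 CPM, which hold 35.8% and 30.8% of the variance. Library 1 lies apart along the first axis and library 7 along the second.

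The second component was related to the slope of each library on gene length. Each library's deviation from the mean was regressed on log2 gene length, and the slopes ran from -0.0262 in library 9 to 0.0248 in library 4 per doubling of length. Length accounted for little of the deviation within a library, with a correlation across genes between -0.0940 and 0.0899. Across libraries, the second component and this slope had Pearson r = -0.910 (permutation p = 0.00031, adjusted p = 0.00248, 2-sided, n = 10). Spearman rho was -0.842 (permutation p = 0.00376, adjusted p = 0.0301), and r was -0.848 without the 2 libraries farthest from the median slope. It was also related to the share of counts in the 10 most abundant genes by r = 0.807 (permutation p = 0.00564, adjusted p = 0.0226), with rho = 0.745 (permutation p = 0.0172, adjusted p = 0.0688). Without the 2 farthest libraries that r was 0.593, and among genes of at least 5 CPM it was 0.328, while the first component had -0.786. The other 6 of the 8 relations computed, of both components with total counts, genes detected and these measures, had adjusted p between 0.139 and 0.461 for r and between 0.0870 and 0.587 for rho. Scores and slopes came from the same counts, so they are not independent measurements. Among genes of at least 5 CPM the slope had r = 0.900 with the first component and -0.362 with the second. Components were numbered by their share of variance within each setting, so the first 2 may have changed order there. Whether they did was not tested.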

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

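The module scores were defined after the data had been seen. Among 19 measures of the libraries, namely 5 library measures, 6 module scores, 4 principal component scores and the log2 CPM of the 4 named genes, 1 had a library far from the others. Chance gives about 1 in 20 for measures not chosen on these data, which does not hold for module scores, components or genes picked for their spread. The measure was the score of module 3, where library 10 lay at -2.47 and the gap to the next library was 0.839 of the whole range, which restates how the module was formed, from genes that share the low level in library 10. Over all 17951 genes tested, 1014 (5.65%) had a single library past the same bound, near the 5% that chance gives. These genes were spread unevenly over the libraries. Library 10 was the lone low library in 241 genes and the lone high library in 102, and library 1 in 157 and 128. Library 3 was alone low in 11 genes and alone high in 7.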

How the results depend on the processing

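The running-median trend, the removal of the length trend, the removal of libraries 1 and 7, the use of the deposited RPKM, the principal components without each library in turn and without the variable genes, and all settings of the modules were chosen after seeing the data. The 1213 variable genes became 296 by DESeq2 dispersion outliers, all of them among the 1213, and the cause was not tested. They became 4200 with the running-median trend, which is a lower trend by construction. The limma-voom F test called 0, with 1124 of 17951 genes at an unadjusted p under 0.05. Its prior of 2.57 degrees of freedom was fitted to the variances of these same genes, the variable ones included, which makes a call hard to reach. Without each library in turn the count lay between 1113 and 1191, and under the other settings between 877 and 1435. Scaling by DESeq2 size factors kept 1207 of the 1213 genes, library size alone 1169, the first component as a covariate 937 and the removal of libraries 1 and 7 821. The 6 modules became 2 among the genes that held without each library in turn, which are fewer genes, and between 3 and 6 without each library in turn, with 3 without library 3 and 3 without library 10. Other settings gave 5 to 9. Both components together held 66.6% of the variance, 62.5% to 71.2% without each library in turn, 56.1% without the variable genes and 66.6% to 74.7% otherwise, while 100 permuted data sets per setting reached at most 23.9% to 29.0%. With the 1000 most variable genes the first component's r with the top-10 share became 0.0178 and with the length slope -0.00311. With genes of at least 5 CPM the second component's r with genes detected became 0.0356. None of these 3 had passed the test, and the cause was not tested. Genes detected passed the test with r = 0.849 for the first component at 5 CPM and -0.800 for the second with the 1000 genes. Components were numbered by share of variance within each setting, so the first 2 may have changed order at 5 CPM. The settings fixed beforehand for gene lists, list relations, duplicated genes and list levels were not run, since no identifier matched a name. Depth limits genes near 0.131 CPM, the highest floor.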

Other observations

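The tests of gene length, of scaling, of a material of fixed composition and of a component among other sources were chosen after the results were seen. In module 1, the 490 genes low in libraries 7, 9 and 10, the level of each gene lay near a single profile over the libraries: the median coefficient of variation was 53.7%, and around a straight line on the summed profile of the other module genes it was 12.9%, against 12.3% for uncalled genes matched on abundance. A trend on gene length is argued against as the whole cause by its size. The slopes were 0.0248 in library 4 and -0.0250 in library 7 per doubling of length. The module's median log2 ratio between these libraries was 2.06. With slopes so small, it adds little that 95.5% of the module's calls remained with the trend removed. At least 94.1% remained under library size alone and DESeq2 size factors, so the calls did not rest on the choice among these scalings. Whether a component is the only source of these genes was not decided. The log2 ratio of library 4 to library 7 had an SD of 1.02 over the module's genes, 2.15 times that of matched genes. The matched genes were all uncalled and so had been selected for low spread, which raises this figure. A component that shares these genes with the rest of the tissue and entered the libraries in different amounts stays open, since the spread around the profile, 1.05 times that of matched genes, decides nothing: the module was built on correlation over the same libraries, so this and co-regulation cannot be told apart. No biological explanation was tested, since the design holds 1 group and the gene lists could not be matched to the identifiers.

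The 458 genes of module 2, high in libraries 1 and 7, lay less near a single profile, with a median coefficient of variation of 99.7% and of 29.1% around the profile of the other genes. A gene-length trend is argued against as the whole cause by the slopes of the 2 libraries. They were small and of opposite sign, at 0.0138 per doubling in library 1 and -0.0250 in library 7, while the module was high in both. With slopes so small, it adds little that 99.8% of the calls remained with the trend removed. In the 293 genes raised at least 3-fold in both libraries, the excess over the gene's median was compared. The log2 ratio of the excess in library 1 to that in library 7 had an SD of 0.77. Matched genes had an SD of 0.55 in the plain log2 ratio of the 2 libraries, so the quotient of 1.39 sets unlike measures side by side. Choosing genes raised in both also narrows the ratio of excesses. The spread of all 458 genes around the profile, 1.81 times that of matched genes, depends on the clustering. A material of fixed composition, a single component and several therefore cannot be told apart. No biological explanation was tested.

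Genes in neighbouring rows of the count table varied together more than genes in shuffled rows. The mean correlation over the 10 libraries was 0.0754 between neighbouring tested rows, 0.0249 at a distance of 2 rows, 0.00716 at 5 rows, 0.0156 at 10 rows and 0.00256 at 50 rows, and was at most 0.0118 in 100 shuffles of the rows (correlations across genes, which are not independent replicates). Similar abundance of neighbours is argued against, since neighbouring rows exceeded pairs matched on abundance by 0.0712. The variable genes alone are argued against as well, since without them neighbouring rows exceeded shuffled rows by 0.0628. A hypothesis left open is that the row order follows the position of the genes, and that neighbours may share regulation or reads, which was not tested for want of coordinates for these identifiers.

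A total of 90 pairs of neighbouring rows belonged to the same module, against a mean of 25.5 and at most 41 in 1000 shuffles of the rows. Module 1 had 36 such pairs against a mean of 13.5 in shuffled rows, module 2 had 41 against 11.5, module 3 had 9 against 0.36 and module 4 had 4 against 0.24. Modules 5 and 6 had 0.

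In 31 genes at least 1 library held 5 CPM or more while another held 0 counts. With the deposited RPKM scaled back to counts, the median BCV was 0.178 in place of 0.152, and 0.131 in place of 0.0990 among genes of at least 100 CPM.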
